A study of Glycine max with 46 samples.

How the data were processed

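RNA sequencing values were taken from 2 deposited tables, 1 with 38 libraries of different lines and tissues and 1 with 8 libraries of hilum and seed coat without hilum. The values in both tables are RPKM computed by the authors: reads per kilobase of cDNA and per M alignments (M, mega) counted over all 88647 transcript models. Per the labels the reads were mapped with Bowtie, whose version, settings and genome build are not given in the sources used here. Each value times the cDNA length and the library total gave a whole number of reads within 0.01 reads (100% of values in every library), so the total of counted alignments per library was recovered from the tables. It ranged from 18.1 M to 545.0 M over all libraries and from 78.3 M to 545.0 M in the hilum table. A read that matches several models or gene copies can be counted in several rows, so near-identical genes such as the chalcone synthase copies are not separately resolved. A count of 0 allows up to 3 reads, and such limits cover counting error only.

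Each of 56044 genes was represented by its model with the longest cDNA, with the description given in the tables (45817 genes, 81.8%, had one). The annotation supplied with the data did not share gene IDs with the tables, so no coordinates are given. The 4 columns of values that no sample label describes were left out. Groups followed line, tissue and, where libraries shared it, stage. In the line series each line had 1 library per stage, and stages served as replicates.

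Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend) on log2(RPKM + 1), over genes with a mean RPKM of at least 1 in the libraries fitted, with a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Hilum and stage were fitted together over 8 libraries, and their interaction over the 4 group means. T157 against Richland was fitted over 8 libraries with stage as a block. W44 and W55 against W43 were fitted together over 12 libraries with stage as a block. The difference between the T157 and W44 effects was fitted over 18 libraries, and W55 5-6 mg coats against whole seed over 4. Other tables and figures were made with python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Library numbers in the hilum titles fall into separate series. Deviations from group means correlated within the series at 0.44 to 0.66, so the series was tried as a block.

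Gene lists were fixed from the descriptions before the data were examined: chalcone synthase (24 genes), general phenylpropanoid (16), anthocyanin and flavonol (36), lignin (81), secondary cell wall (165), cell wall loosening and pectin (440), proline-rich and hydrophobic seed coat proteins (267), RNA silencing (42), photosynthesis (175), histones and cell cycle (290), defence (933), heat shock (453), flooding and low oxygen (43), cotyledon and embryo (475), trypsin inhibitor and lipoxygenase (105) and ribosome (708). Lists for proanthocyanidin and isoflavonoid matched 0 genes and gave no result. The cotyledon and embryo list holds 167 lipid-transfer and 2S albumin descriptions, 145 late embryogenesis and 91 cupin descriptions, many of which are also expressed in coats. Lists were tested against all other genes with camera (limma) with a preset correlation of 0.01 and with an estimated correlation, and adjusted over the lists within a comparison. "Adjusted over the list alone" means Benjamini-Hochberg over the members of the list.

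Named genes follow a rule fixed before the data were examined. In replicated comparisons these are the 10 most raised and 10 most lowered called genes with a description, a mean RPKM of at least 5 in the higher group and the same sign in every pair or library. To these were added up to 3 called members per list, or the 2 most abundant where none was called, the chalcone synthase members with a mean RPKM of at least 5, and the genes lost in W55. In comparisons of single libraries they are the 5 highest and 5 lowest log2((a + 1)/(b + 1)) among genes with an RPKM of at least 10 in the higher library. The flanking genes of the chromosome 8 run, Glyma.08G109600, and the leaf chalcone synthase genes Glyma.19G105100 and Glyma.06G118500 were named after their values were seen. Random lists for single libraries (10000 per list) were drawn from 20 bins of expression.

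Chalcone synthase RPKM was summed over the 24 genes, over 9 chromosome 8 copies and over 2 copies on chromosomes 1 and 11, and compared by exact two-sided permutation (hilum) or exact sign-flip tests (pairs of lines). A read that matches several copies can enter such a sum more than once. The sums and the shares of copy groups in them are therefore not shares of separate transcripts. The run of genes lost in W55 was the longest stretch of expressed neighbours, by gene ID, with at most 5% of the control RPKM in 3 pairs.

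The fit was tested on simulated data with a dispersion of 0.1 and 200 changed genes. Of the genes changed 4-fold it recovered 98 of 100 in the hilum design, 97 for T157, 100 for W44, 83 for W55 and 79 for the W55 whole seed design. Of those changed 2-fold it recovered 22, 22, 26, 9 and 4 of 100, with 5, 4, 4, 2 and 10 false calls. These recoveries hold for the simulated spread only. In the real fit of T157 no gene was called, although members of the chalcone synthase list stood more than 4-fold higher. A real fit without calls therefore does not show that changes of 4-fold were absent.

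Alternatives were a pseudocount of 0.1, no filter on low values, rescaling by the median ratio, leaving out each library, blocks on the library series or on replicate numbers, fits without the stage block, the 5 DAF whole seed pair added to T157 and Richland, the W44 library at 75-100 mg added, adjacent W44 pairs only, and only the 4 late W43 and W55 libraries. Added after the data were seen were the model numbered 1 of each gene, scaling without 369 undescribed chromosome 13 models, scaling over described models only, a 20% limit without the root pair for the lost run, and rescaled or reduced sums of the line pairs, also scaled over described models.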

Results

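Messenger RNA was measured in 46 soybean (Glycine max) libraries that fell into 24 groups by line, tissue and, for some tissues, stage. The seed coat, the maternal tissue around the embryo, was sampled at stages given as the fresh weight of the whole seed. Series of seed coats came from Richland (4 libraries), its pigmented mutant T157 (4), the Williams line W43 (5) and the pigmented Williams mutants W44 (6) and W55 (2), with 1 library per line and stage. The hilum, the scar where the seed joins the pod, was dissected from the rest of the Williams seed coat at 25-50 mg and at 50-100 mg, with 2 libraries per tissue and stage. Groups of 2 W55 libraries held seed coats of 5-6 mg seeds and whole seeds taken 5 days after flowering (DAF). Young leaf, young root, flooded root, flower, T157 and Richland whole seed, and the seed coats of UC9, UC501, UC508 and RM38 had 1 library each. The libraries held 18.1 M to 545.0 M counted alignments, so a single read in a model of 1 kb stood for an RPKM of 0.00183 to 0.0553. The lines differ at the I locus, where duplicated chalcone synthase genes give rise to small interfering RNAs that silence chalcone synthase, the first committed enzyme of flavonoid pigment synthesis. Dominant forms give a yellow coat, or a yellow coat with a black hilum as in W43, and the recessive i mutations give a pigmented coat. The gene IDs carry the chromosome number before the letter G, and no coordinates were available for them.

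The black hilum was compared with the yellow remainder of the same coats, to see what separates the pigmented from the unpigmented part. Chalcone synthase transcripts were lower in the hilum. Summed over the 24 listed genes they reached an RPKM of 67.0 ± 22.4 in the hilum and 182.6 ± 94.6 in the coat (SD, n = 4 libraries per tissue), a 2.58-fold difference of geometric means (log2 −1.37). The hilum libraries spanned 41.1 to 93.9 and the coat libraries 98.1 to 308.0, without overlap (exact two-sided permutation test over 70 assignments, p = 0.0286, the smallest it can give). Rescaling by the median ratio left log2 −1.25 but brought the ranges to overlap, at 44.4 to 96.5 and 92.5 to 279.0, with an exact permutation p of 0.0571. Leaving out any hilum library, or either 25-50 mg coat library, gave an exact permutation p of 0.0571 with log2 −1.07 to −1.55, over fewer assignments and still without overlap. The 9 chromosome 8 copies differed by log2 −1.45 (exact permutation p = 0.0286) and the chromosome 1 and 11 copies by −1.37, with overlap between stages (hilum up to 42.92, coat down to 42.05; p = 0.0571). Between hilum and coat of the same stage and library series, compared after the data were seen, each of these sums was lower in 4 of 4 pairs, as deposited and rescaled (exact sign-flip p = 0.125, the smallest that 4 pairs allow). Of 14 tested genes of the family 12 fell and 0 rose (limma), among them Glyma.01G228700 on chromosome 1 (log2 −1.34 ± 0.17 SE, adjusted p = 0.000991) and Glyma.08G109300 on chromosome 8 (−1.26 ± 0.14, adjusted p = 0.000573). Reads that match several near-identical copies were counted in several rows, so the members are not separate measurements.

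The natriuretic peptide gene Glyma.06G069400 reached an RPKM of 64.2 ± 16.3 in the hilum and 0.0572 ± 0.0728 in the coat (SD, n = 4 each; log2 5.91 ± 0.18 SE, adjusted p = 3.35e-06). A peroxidase (Glyma.19G091800, log2 5.91 ± 0.21) and xylem cysteine peptidase 2 (Glyma.04G014800, 4.72 ± 0.34), a protease of dying xylem cells, were also far higher. Of 83 tested secondary cell wall genes 46 rose and 11 fell (camera adjusted p = 0.121 with an estimated correlation), including cellulose synthase A4 (Glyma.09G051100, 2.85 ± 0.50) and a fasciclin-like arabinogalactan protein (Glyma.15G086100, 3.77 ± 0.35). Of 23 lignin genes 10 rose and 6 fell. The laccase Glyma.03G077900 was higher by 2.65 ± 0.23, while laccase 14 (Glyma.11G236800) was lower, at −2.37 ± 0.32. Of 10 general phenylpropanoid genes 3 rose, 4-coumarate:CoA ligases such as Glyma.13G372000 (1.40 ± 0.12), and 1 fell. Of 23 anthocyanin and flavonol genes 1 rose and 5 fell, among them the chalcone isomerases Glyma.06G143000 (−1.81 ± 0.24) and Glyma.04G222400 (−1.62 ± 0.19).

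Among the genes lower in the hilum, expansin A2 (Glyma.03G035800), which loosens walls of growing cells, had an RPKM of 6.10 ± 7.85 in the hilum and 272.8 ± 85.7 in the coat (SD, n = 4 each; log2 −5.81 ± 0.68 SE, adjusted p = 0.000672). The gibberellin-regulated genes Glyma.13G039600 and Glyma.13G039300 stood at log2 −5.03 ± 0.33 and −5.01 ± 0.34. Of 144 wall-loosening and pectin genes 43 rose and 43 fell, and the xyloglucan endotransglucosylase gene Glyma.11G193600 went the other way (4.23 ± 0.23). Of 209 histone and cell cycle genes 10 rose, 71 did not pass and the others fell, led by histone H2A 10 (Glyma.13G285900, −3.18 ± 0.25). Of 612 ribosomal protein genes 420 fell and 11 rose. Of 132 photosynthesis genes 52 fell and 2 rose. Of 28 RNA silencing genes 9 fell and 3 rose, among them dicer-like 2 (Glyma.09G025300, −0.62 ± 0.13).

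Alcohol dehydrogenase 1 genes, used in fermentation, split. Glyma.13G035200 was lower (log2 −4.33 ± 0.33) and Glyma.04G240800 higher (1.00 ± 0.14), and the flooding list as a whole had 4 higher and 2 lower of 27 tested. Of 203 defence genes 60 rose and 40 fell, including chitinase-like protein 2 (Glyma.15G143600, 3.34 ± 0.43, RPKM 322.7 in the hilum). Of 280 heat shock genes 34 rose and 45 fell. Of the proline-rich and hydrophobic protein genes 21 rose, 33 fell and 73 did not pass. The cotyledon and embryo list had 57 higher and 39 lower of 177. Its strongest members, such as Glyma.03G073500 (5.33 ± 0.30) and Glyma.02G281400 (−4.02 ± 0.34), share a description that covers lipid-transfer proteins and seed albumins alike. Of 45 trypsin inhibitor and lipoxygenase genes 3 rose and 26 fell.

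**Figure D1:**
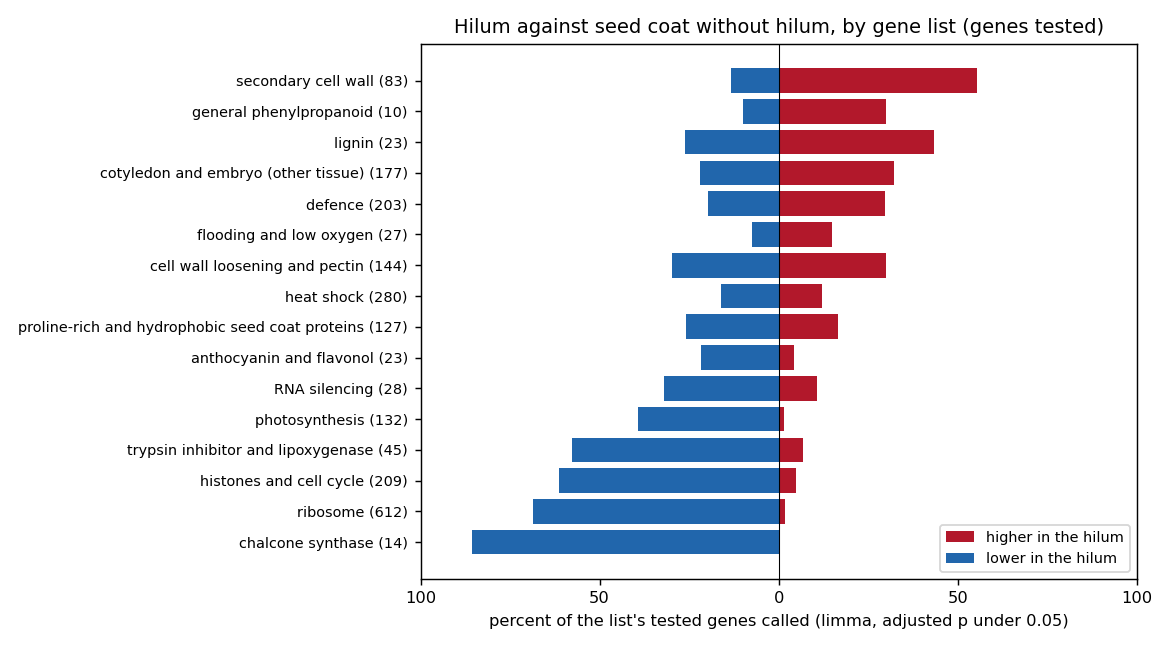
Percent of each list's tested genes called higher (red, right) or lower (blue, left) in the hilum than in the seed coat without hilum (limma, 8 libraries; genes tested in parentheses). Of the secondary cell wall genes 46 are higher and 11 lower, of the ribosome genes 11 and 420, and of all genes 3930 and 7794 (5571 and 5374 after rescaling); no list passed camera with an estimated correlation (adjusted p = 0.121 for both lists).

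In all, limma called 11724 of 29296 genes different between hilum and coat, 3930 higher and 7794 lower, against 14535 at an unadjusted p under 0.05. The median of all genes lay at log2 −0.11, and rescaling by the median ratio turned the split from 33.5% higher to 50.9% higher (5571 higher, 5374 lower), with 9304 calls shared in sign. Relative to that median, the list medians were 0.72 for secondary cell wall, 0.41 for lignin, −0.39 for ribosome, −0.51 for histones and −1.13 for chalcone synthase. With the preset correlation, camera placed secondary cell wall (adjusted p = 4.23e-10), lignin (0.00882), defence (0.000329) and the cotyledon list (0.000384) toward the hilum. It placed ribosome (2.13e-15), histones (1.87e-07), chalcone synthase (3.17e-05), trypsin inhibitors (0.000384) and photosynthesis (0.00066) toward the coat. No list call held with an estimated correlation: adjusted p = 0.121 for secondary cell wall, lignin, ribosome and trypsin inhibitors with an estimated correlation, and 0.269 to 0.626 for the others. After rescaling lignin no longer passed (adjusted p = 0.0761). The wall-loosening list had a median of −0.08, a mean of 0.05 and a camera direction toward the hilum, the heat shock list a median of −0.03, a mean of −0.01 and the same direction, the flooding list a median of 0.11 and a mean of −0.16, and the proline-rich list a median of −0.12, a mean of −0.09 and a direction toward the hilum. When adjusted over the list alone, 50 secondary wall genes were higher and 13 lower, and 451 ribosomal genes were lower. The log2 fold changes of the 2 series of library numbers correlated at r = 0.938 across genes, which are not independent replicates.

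Between the 25-50 mg and 50-100 mg stages of the same dissections a BURP domain gene (Glyma.08G230600), of a plant-specific protein family, rose by log2 2.23 ± 0.36 (limma, RPKM 7.87 ± 2.69 to 42.7 ± 18.7, SD, n = 4 libraries per stage, adjusted p = 0.0474). Paired temperature-induced lipocalin genes, Glyma.04G180600 and Glyma.15G205900, rose by 1.26 ± 0.18 and 1.24 ± 0.18. The glucose-methanol-choline oxidoreductase Glyma.05G050100 stood at −2.78 ± 0.28 and the subtilases Glyma.20G152600 and Glyma.10G241600 at −1.94 ± 0.23 and −1.80 ± 0.25. Of 209 histone and cell cycle genes 14 fell and 0 rose, and 97 fell when adjusted over the list alone. Of 14 chalcone synthase genes 1 fell, Glyma.01G228700 (−0.98 ± 0.17, adjusted p = 0.0495), and 12 fell when adjusted over the list alone. Both lists passed camera with the preset correlation (adjusted p = 1.38e-12 and 6.43e-09), and gave adjusted p = 0.327 and 0.352 with an estimated correlation. In all 113 genes rose and 200 fell. The count was not stable, at 0 without the filter on low values, 2632 with the library series as a block, and 1 without hilum 25-50 mg replicate 1, 32 without coat 25-50 mg replicate 2, 50 without coat 50-100 mg replicate 2 and 0 without any other library.

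The tissue difference itself changed with stage for 4 genes (limma, 1365 at an unadjusted p under 0.05). A peroxidase (Glyma.16G200300), a plasma membrane water channel (Glyma.18G198300) and a cupredoxin (Glyma.05G076700) had their hilum excess grow by log2 2.12, 2.01 and 1.90. In the hilum they went from RPKM 6.67 ± 0.464 to 32.1 ± 2.07, from 6.23 ± 0.244 to 29.2 ± 1.74 and from 12.2 ± 0.531 to 46.6 ± 0.203 (SD, n = 2). A second peroxidase, Glyma.11G161600, moved the other way (−2.90), from 15.7 ± 1.97 to 3.42 ± 0.657 in the hilum and from 18.5 ± 0.290 to 37.6 ± 0.250 in the coat. When adjusted over the list alone, 26 of 209 histone and cell cycle genes also differed, all with a positive change. Of 23 lignin genes 5 had a positive and 3 a negative change. The defence list had 1 and 4, the cotyledon and embryo list 2 and 2, and the wall-loosening list 3 and 0. The anthocyanin and flavonol list and the trypsin inhibitor and lipoxygenase list had 1 and 0 each. The count of all genes was 0 without any 1 library and 0 with a pseudocount of 0.1, and 93 with the library series as a block.

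T157, a pigmented i mutant of Richland, was compared with Richland over 4 matched seed coat stages. Chalcone synthase transcripts were higher in T157 at every stage, at a summed RPKM of 584, 946, 353 and 185 against 141, 104, 48.4 and 47.1, a mean log2 ratio of 2.52 ± 0.60 (SD, n = 4 pairs; 5.74-fold). The chromosome 1 and 11 copies carried most of it, at 9.21-fold (log2 3.20 ± 0.75, 4 of 4 pairs), while the chromosome 8 copies were 2.28-fold higher (1.19 ± 0.33, 4 of 4 pairs). With 4 pairs an exact sign-flip test cannot go below p = 0.125 (two-sided), which these sums reached. In limma none of the 29080 tested genes passed (0 calls, smallest adjusted p = 0.137, 4647 at an unadjusted p under 0.05, and 0 calls after rescaling). Adjusted over the list alone, all 14 chalcone synthase genes were higher, led by Glyma.01G228700 (RPKM 256 ± 177 against 25.1 ± 14.8, SD over 4 stages; log2 3.18 ± 0.29 SE) and Glyma.11G011500 (3.05 ± 0.30).

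Other flavonoid genes differed less. Adjusted over the list alone, 1 of 24 anthocyanin and flavonol genes was higher and 3 were lower, and flavanone 3-hydroxylase (Glyma.02G048400) stood at log2 −0.36 ± 0.22. Of 10 general phenylpropanoid genes 4 were higher over the list alone, and of 49 trypsin inhibitor and lipoxygenase genes 7 were higher and 2 lower, with lipoxygenase 1 (Glyma.15G026400) at 1.10 ± 0.24 in 4 of 4 pairs. The log2 fold change was positive for 573 of 603 ribosomal protein genes, with a median of 0.21, and for 20 of 115 photosynthesis genes, with a median of −0.16. By camera with the preset correlation chalcone synthase (adjusted p = 4.8e-19) and ribosome (1.66e-24) were higher and photosynthesis (1.32e-05) and defence (0.013) lower, each with adjusted p = 0.788 with an estimated correlation. Adjusted over the list alone, 11 wall-loosening and pectin genes were lower and 4 higher, and 11 cotyledon and embryo genes were higher and 3 lower.

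W44, an i mutant of Williams labelled as carrying an inversion, was compared with W43 over 5 matched stages. The chalcone synthase sum was higher in W44 at every stage, at an RPKM of 963, 740.4, 380.0, 117 and 167 against 159, 185, 194.2, 74.8 and 98.8, a mean log2 ratio of 1.39 ± 0.86 (SD, n = 5 pairs; 2.63-fold). This gave an exact sign-flip p of 0.0625 (two-sided), the smallest that 5 pairs allow. The chromosome 1 and 11 copies were 4.46-fold higher (log2 2.16 ± 0.96, 5 of 5 pairs), at 9.65-fold at 10-50 mg, 1.69-fold at 300-400 mg and 5.21-fold at 400-500 mg. The chromosome 8 copies were higher in 4 of 5 pairs (0.67 ± 0.69, exact sign-flip p = 0.125). The lower pair, at 50-100 mg (−0.24), held the W44 library with 55.4% of alignments in models without a description, and stood at 0.82 when scaled over described models and 0.76 after rescaling. The whole sum of that pair went from 1.96-fold to 4.07-fold and 3.91-fold. The median of all genes lay at log2 −0.12. After rescaling by the median ratio, Glyma.01G228700 was higher by log2 2.27 and Glyma.11G011500 by 2.20. Adjusted over the list alone, 11 of 13 chalcone synthase genes were higher, with camera adjusted p = 2.86e-28 at the preset correlation and adjusted p = 0.251 with an estimated correlation.

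Flavanone 3-hydroxylase went the other way in W44. Glyma.02G048400 and Glyma.02G048600, which act just after chalcone isomerase, were lower in 5 of 5 pairs, at log2 −1.46 ± 0.38 and −1.45 ± 0.36 (−1.30 each after rescaling). Of 22 anthocyanin and flavonol genes 9 were lower when adjusted over the list alone (camera adjusted p = 2.38e-08, and adjusted p = 0.533 with an estimated correlation). Photosynthesis genes had a positive log2 fold change in 6 of 121 (camera adjusted p = 3.1e-12, and adjusted p = 0.969 with an estimated correlation). The defence list passed camera in the other direction (adjusted p = 5.94e-07, and adjusted p = 0.969 with an estimated correlation), with a median of 0.01 and a mean of −0.002. Over all 28909 genes limma made 0 calls (smallest adjusted p = 0.255, 1658 at an unadjusted p under 0.05, 0 after rescaling). The count was 1 without W44 at 300-400 mg, W44 at 400-500 mg or W43 at 400-500 mg, and 2 with the 10-50 and 50-100 mg pairs alone. In the W44 library at 50-100 mg 55.4% of alignments fell in transcript models without a description, against 6.69 to 8.87% in the other W44 libraries.

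**Figure D2:**
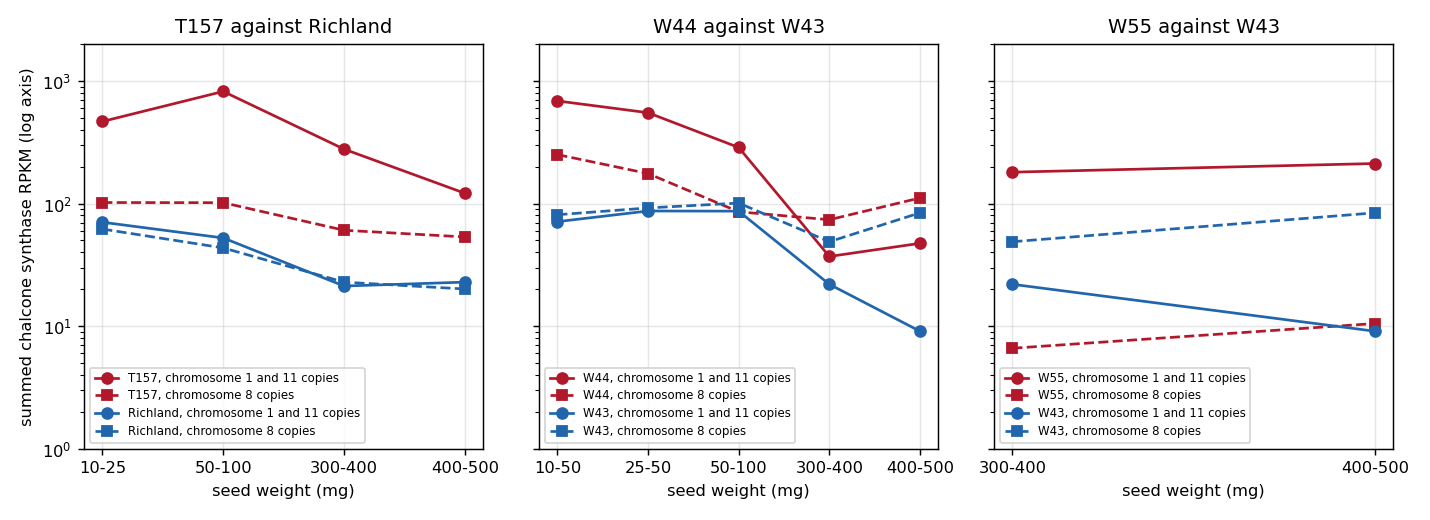
Summed chalcone synthase RPKM (log axis) by seed weight in mg for 3 pairs of lines, 1 library per point, with the chromosome 1 and 11 copies as solid lines and the chromosome 8 copies as dashed lines. The mutants (red) lie above their control lines (blue) for the chromosome 1 and 11 copies at every stage, and the W55 chromosome 8 copies lie below W43 at 6.61 and 10.5 against 48.8 and 84.0.

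The difference between the effects of the mutations in T157 and in W44 was tested directly, over 18 libraries. No gene passed (limma, 0 calls of 29222, smallest adjusted p = 0.152, 1513 at an unadjusted p under 0.05, 0 after rescaling). Glyma.01G228700 differed by log2 1.07 ± 0.51 (adjusted p = 0.881). Ribosome genes leaned toward T157 and defence genes toward W44 in camera (adjusted p = 4.49e-08 and 4.37e-08, each adjusted p = 0.884 with an estimated correlation). The median of all genes lay at log2 0.12. The count was 2 with a pseudocount of 0.1, and 1 without T157 at 10-25 or 400-500 mg or Richland at 10-25 or 400-500 mg.

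W55, labelled as carrying a 138 kb deletion at the I locus, had both directions within the chalcone synthase family when compared with W43 at 300-400 and 400-500 mg. The genotype label of these 2 W55 coats reads i-i, while their cultivar label gives an i mutation, and they were treated as W55. The chromosome 1 and 11 copies reached a summed RPKM of 180.2 and 212 against 22.0 and 9.09, which is 8.21-fold and 23.3-fold higher. The chromosome 8 copies reached 6.61 and 10.5 against 48.8 and 84.0, or 13.5% and 12.5% of W43. The limma fit covered 12 libraries, so the W43 level and the spread also drew on earlier stages and on W44, while W55 had 2 libraries. With the 4 late W43 and W55 libraries alone it made 0 calls. In the fit over 12 libraries 2 of 13 tested genes rose, Glyma.01G228700 (log2 3.97 ± 0.52 SE, adjusted p = 0.011) and Glyma.11G011500 (3.86 ± 0.50). In the same fit 9 fell, all on chromosome 8, such as Glyma.08G110300 (−2.06 ± 0.34, adjusted p = 0.0304). After rescaling their folds hardly moved (4.03, 3.92 and −1.98) but the calls ended, each at adjusted p = 0.0699. The whole family gave camera adjusted p = 1.01e-11 toward W43, and adjusted p = 0.992 with an estimated correlation.

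Non-family genes between and beside the chromosome 8 copies were also low in W55. DNAJ-like 20 (Glyma.08G109700), a chaperone gene, had an RPKM of 19.3 and 19.5 in W43 coats and 0.163 and 0.180 in W55 coats, and 4.10 in W54 root against 0.0273 in W55 root. It was the only gene of 22027 expressed ones with at most 5% of its partner in both coat pairs and the root pair. Without the root pair the longest run grew to 3 genes, adding the cysteine-rich peptide gene Glyma.08G109800 (6.93 and 4.86 against 0.0297 and 0.0290, the last from 2 reads each) and the cytochrome P450 Glyma.08G109900. The last was listed at 0 in both W55 coats, which allows an RPKM of up to 0.0173 and 0.0169 (3 reads), against 3.10 and 4.10 in W43. With a limit of 20% and without the root pair, a setting chosen after the data were seen, the run held 16 expressed genes, from Glyma.08G109200 to Glyma.08G110900. Just outside, the UDP-glucuronate epimerase Glyma.08G109100 went from 18.8 to 9.08 at 300-400 mg, and beta galactosidase 9 (Glyma.08G111000) from 6.43 to 7.51. Glyma.08G109700 was listed at 0, which allows up to 3 reads, in each of the 2 W55 coats of 5-6 mg and the 2 W55 whole seed libraries. It stood at 0.307 in UC9 and 0.160 in RM38 (3 reads), Clark lines with i mutations, against 7.64 in UC501, a Harosoy line. RM38 was sampled at 25-50 mg and the others at 5-6 mg. The run was not uniformly low in RM38. There Glyma.08G110600 stood at 4.00 (UC9 0.838, UC501 4.07) and Glyma.08G109800 at 1.47 (UC9 0.0676, UC501 41.7).

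**Figure D3:**
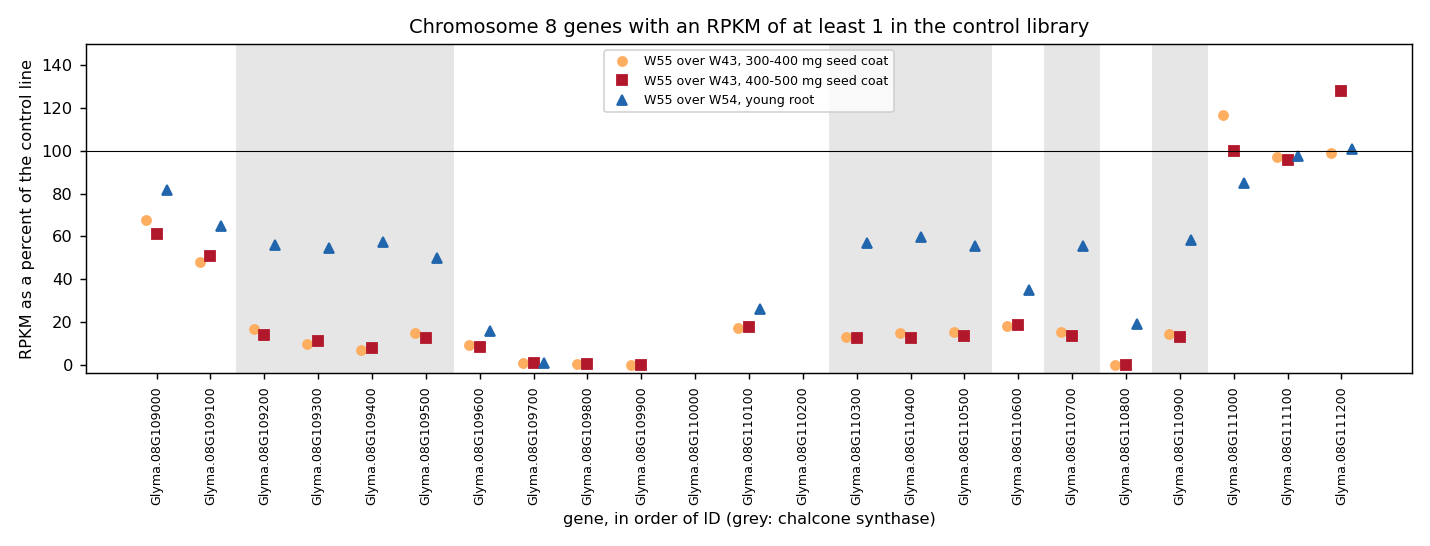
RPKM in W55 as a percent of the control line (W43 for seed coats, W54 for young root) for neighbouring chromosome 8 genes in order of ID, 1 library each, where the control has an RPKM of at least 1. In the coats the genes from Glyma.08G109200 to Glyma.08G110900 lie at or under 20%, and in the root the chalcone synthase copies together lie at 56.2%.

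Outside that run, cysteine peptidase XBCP3 (Glyma.08G116300), also on chromosome 8, was higher in W55 (66.9 and 144 against 2.16 and 8.97, limma log2 4.25 ± 0.72, adjusted p = 0.0347). So were the Kunitz trypsin inhibitors Glyma.08G341500 (3.31 ± 0.41) and Glyma.01G095000 (3.22 ± 0.32). Of 188 cotyledon and embryo genes 5 rose and 8 fell, or 8 and 20 when adjusted over the list alone, with the cupin Glyma.10G037100 at 3.39 ± 0.51 and a list median of 0.01 against a mean of −0.04. The late embryogenesis gene Glyma.03G189200 (−3.65 ± 0.54) and galactinol synthase 1 (Glyma.03G222000, −3.29 ± 0.61), both of seed drying, stood at RPKM 119 and 54.4 in W43 at 400-500 mg but 5.25 and 1.86 in W43 at 300-400 mg. Of 121 photosynthesis genes 84 had a positive log2 fold change (camera adjusted p = 6.25e-08, and adjusted p = 0.992 with an estimated correlation). In all limma called 88 of 28909 genes, 22 higher and 66 lower, with 1235 at an unadjusted p under 0.05. After rescaling 6 genes were called (1 higher, 5 lower; 5 calls shared), none of the preceding genes among them, and 4 lay in the chromosome 8 run, among them Glyma.08G109700 (−4.17 ± 0.20) and the RNA-binding protein gene Glyma.08G109600 (−2.52 ± 0.13), both at adjusted p = 0.00131. The count was 0 without W55 at 400-500 mg, 12 without W44 or W43 at 50-100 mg and 0 with the 4 W43 and W55 libraries alone, and 1.88 times as high without W44 at 400-500 mg and 1.68 times without W43 at 300-400 mg.

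Within W55, the seed coats of 5-6 mg seeds were compared with whole seeds at 5 DAF. The log2 fold changes of genes in this paragraph are those after rescaling by the median ratio, and RPKM values are as deposited. Rescaled values are given because the median of all genes fell by 1.80 on the log2 scale as deposited. After rescaling 5832 genes were higher and 5658 lower in the coats, against 420 and 23728 of 24841 tested as deposited (limma, 24148 calls, 24153 at an unadjusted p under 0.05). That is 50.8% of calls higher after rescaling against 1.7% as deposited, with 6078 calls shared in sign. Higher in the coats were, among others, an aspartyl protease (Glyma.02G213000, rescaled log2 8.23, RPKM 117 ± 30.1 against 0.121 ± 0.0407, SD, n = 2 each) and the receptor-like protein Glyma.16G174500 (7.88, 1739 ± 37.6 against 94.1 ± 112.5). Lower were, among others, another aspartyl protease (Glyma.04G248800, −6.30, 0.946 ± 0.119 against 856 ± 481), vegetative storage protein 1 (Glyma.08G200000, −3.15, 32.7 ± 2.42 against 2238 ± 534), and embryo-specific protein 3 (Glyma.16G202500, −3.29). Chalcone synthase Glyma.01G228700 was higher in the coats by 4.11. The cyclin D3 gene Glyma.17G167700 (−1.90) and a xyloglucan endotransglucosylase (Glyma.06G302300, −2.01) were lower, and histone H2A 10 (Glyma.13G285900, 7.12) was higher.

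In the 5-6 mg coats 88.3% and 80.1% of alignments fell in models without a description, against 6.03 to 15.85% in all other libraries save the W44 library at 50-100 mg. Of 20 RNA silencing genes all 20 fell as deposited, yet their median lay at only −0.04 relative to all genes, and 206 of 211 histone and cell cycle genes fell with a relative median of −0.59. As deposited, camera with the preset correlation placed anthocyanin and flavonol (adjusted p = 8.71e-10), general phenylpropanoid (1.99e-09) and the cotyledon and embryo list (4.68e-12) toward the coats, although 9 of 21, 2 of 9 and 97 of 130 of their genes were called lower. Each gave adjusted p = 0.792 with an estimated correlation. The median of the anthocyanin list was 0.26 and its mean −0.40. The 4-coumarate:CoA ligases Glyma.15G001700 and Glyma.13G372000 were lower as deposited, at −1.35 and −1.26, and higher after rescaling, at 0.64 and 0.78.

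**Figure D4:**
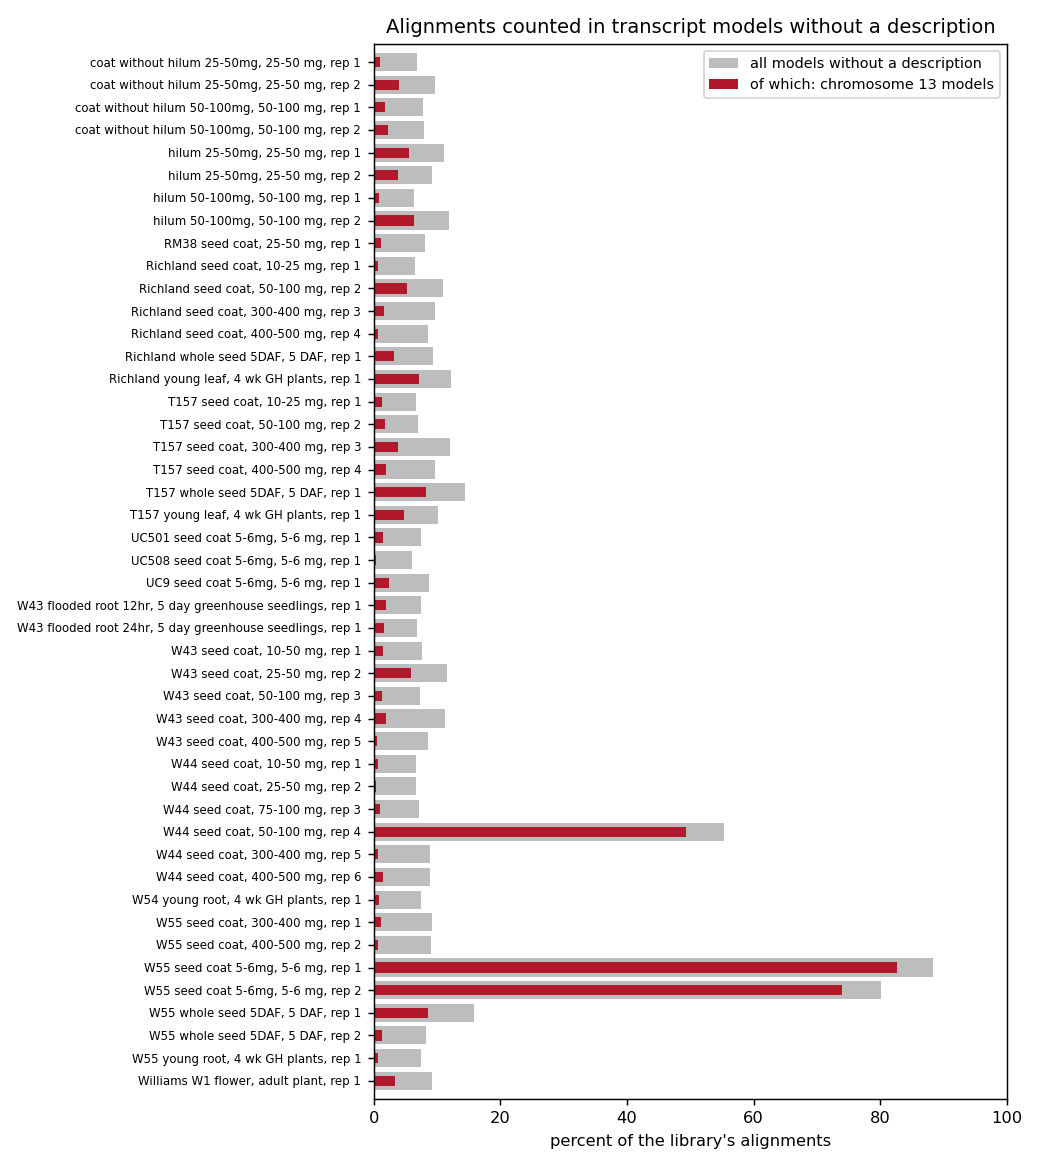
Percent of each library's alignments in transcript models without a description (grey), and in the chromosome 13 models among them (red), for 46 libraries. The W55 seed coats of 5-6 mg reach 88.3% and 80.1% and the W44 seed coat at 50-100 mg reaches 55.4%.

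Some comparisons had 1 library per group, so they carry no test and no replicate check, and the median of each list was placed among 10000 random lists of like expression. In young leaf, T157 over Richland, the chalcone synthase median was log2 1.16, above all random lists (percentile 100). The leaf genes were not the seed coat ones: Glyma.19G105100 and Glyma.06G118500 stood at RPKM 302 and 176 against 104 and 93.3, and Glyma.01G228700 at 4.35 against 1.91. Histone and cell cycle genes were higher (median 1.27, percentile 100) and photosynthesis genes lower (median −1.03, percentile 0.0), in a pair whose median over all genes was 0.25. Protodermal factor 1 (Glyma.02G287400), an epidermal gene, stood at 67.5 against 3.71, and the long-chain fatty alcohol dehydrogenase Glyma.01G152900 at 0.729 against 59.5. In whole seed at 5 DAF, T157 over Richland, the chalcone synthase median was 0.56 (percentile 100) and the secondary cell wall median −0.37 (percentile 0.0). The integrase-type DNA-binding protein genes Glyma.15G180000 and Glyma.09G072000 stood at 0.915 and 1.25 against 35.4 and 28.6.

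UC508, a Harosoy isoline with defective seed coats, differed little from the Harosoy line UC501 at 5-6 mg: 31 of 6871 genes lay above log2 1 and 15 below −1. Alcohol dehydrogenase 1 (Glyma.13G035200) stood at 138 against 21.1, and the flooding list median was 0.19 (percentile 100). The cysteine proteases named senescence-associated gene 12 (Glyma.06G275100 and Glyma.06G273700) stood at 56.2 and 65.6 against 18.1 and 21.6. The chalcone synthase median was −0.09 (percentile 21.8). In young root, W55 over W54, the chalcone synthase median was −0.74 (percentile 0.0), hemoglobin 1 (Glyma.11G121800), which responds to low oxygen, stood at 39.3 against 6.96, and nicotianamine synthase 1 (Glyma.15G251300), of iron transport, at 10.3 against 52.2. In W43 roots flooded for 24 h, against 12 h, the chalcone synthase median was 2.55 (percentile 100), with a sum of 874 against 376. The chromosome 8 copies stood at 527 against 74.1 in sum, and the chromosome 1 and 11 copies at 277 against 288. Beta glucosidase 13 (Glyma.11G129800) stood at 94.4 against 2.18, ribonuclease 1 (Glyma.02G064300) at 41.8 against 323, and the flooding list median was −0.26 (percentile 0.0).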

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

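The tests of swapped tissue labels and of the authors' scaling in the hilum comparison, and the counts of other splits of the libraries, were chosen before the data were examined, and all other tests of explanations given here, and the gene calls after rescaling, were chosen only after the result was seen.

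Over 24 tests of groups and measures for a sample far from the others, 6 tests placed a sample apart, in 4 samples. Chance gives about 1 in 20 such tests among replicates, but each group here was 1 line at different stages. Differences between stages can therefore set a library apart, and several measures of 1 library are not independent. The W44 library at 50-100 mg stood out on 3 measures, with 148.8 M alignments (next highest 121.6 M), 55.35% of alignments in models without a description (next highest 8.87%) and a mean log2(RPKM + 1) of 0.899 over the cotyledon and embryo list (next lowest 1.27). By the way RPKM is built, the share taken by undescribed models lowers every other RPKM of that library. The Richland and T157 libraries at 50-100 mg stood out with 181.5 M and 172.4 M alignments, and the T157 library at 10-25 mg with a mean of 1.18 over the cotyledon and embryo list.

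The hilum excess differed between stages for 4 genes by a test of the difference itself (limma): the peroxidase Glyma.16G200300 (log2 2.12), the water channel Glyma.18G198300 (2.01), the cupredoxin Glyma.05G076700 (1.90) and the peroxidase Glyma.11G161600 (−2.90). None of the 4 calls held when any 1 library was left out. Signals in libraries that no comparison used were the chalcone synthase sums of 749 in the RM38 coat at 25-50 mg and 558 in the UC9 coat at 5-6 mg, and the W44 coat at 75-100 mg, used only in an alternative fit, had 536, each from 1 library, above the highest of the whole W43 coats (194.2).

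Chalcone synthase RPKM was lower in the black hilum than in the yellow coat. Swapped tissue labels are argued against, as the libraries labelled hilum correlated less with whole W43 coats than those labelled coat did, by a difference of −0.074 in mean correlation (0.823 to 0.907 against 0.922 to 0.956). Reads shared between gene copies stay open: the chromosome 8 and the chromosome 1 and 11 copies were both lower, the smaller difference being −1.37, but their ratio stayed at 1.0 to 1.28 over the 8 libraries, so the copies were not resolved from each other. The authors' scaling is argued against as the whole cause: after rescaling the difference was −1.25 and all 12 genes called lower were still called (limma, highest adjusted p = 0.0247), although the summed libraries then overlapped (hilum up to 96.5, coat down to 92.5, of other stages; exact permutation p = 0.0571), which the bound set beforehand did not allow. The tissue difference that the labels name may account for the pattern, and whether the pigment of the hilum was made earlier or from other transcripts was not tested.

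Most genes had a lower RPKM in W55 coats of 5-6 mg than in whole seed. The undescribed chromosome 13 models alone stay open as the whole cause: with them left out of the scaling the median of all genes stayed at log2 −0.57, but that of the 237 genes with a mean RPKM of at least 100 went from −2.22 to −0.07. Low depth is argued against as the cause of the shift for the 237 abundant genes only, and stays open for the less abundant ones. The 5-6 mg coats held 111.3 M and 105.7 M alignments in all, against 78.4 M and 84.3 M in whole seed. The 237 abundant genes, far above the counting floor, fell by −2.22 as deposited, and their fall went with the scaling. The described models alone held 0.237 of the alignments of whole seed. By the way RPKM is built, the share taken by undescribed models lowers every other RPKM of these coats, so it makes up part of the shift. Scaling over described models brought the median to −0.31. The direction of that move was fixed beforehand, so it is no separate test. What these models are, and the difference between coat and whole seed itself, were not tested.

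The chromosome 8 copies of chalcone synthase were low in W55 coats. The authors' scaling is argued against as the cause, because their median log2 fold change was −2.0 as deposited and −1.91 rescaled, over 9 copies. In limma 0 of the 9 were called after rescaling (all 9 were as deposited), where the adjusted p of the named copies lay at 0.0699 to 0.113. Over all genes the calls went from 88 to 6 on rescaling, and to 6 with the chromosome 13 models left out of the scaling. They went to 12 without W44 or W43 at 50-100 mg. That W44 library held 49.34% of its alignments in these models, the other fitted libraries 0.41 to 5.81%. The count of calls thus depended on that pair and on the scaling, and the 9 copies were not traced separately. Loss of every copy cannot be told apart from loss of part of them, since the copies stood at 56.2% of W54 in the W55 root, which was a single library. The ratio of chromosome 8 to chromosome 1 and 11 RPKM varied 36.3-fold over 7 W55 libraries but 2.83-fold outside the root, so reads shared with the chromosome 1 and 11 copies stay open for the coats and seeds. The 138 kb deletion named in the labels stays a possible explanation that these values cannot settle.

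For the hilum count the real split of the 8 libraries gave 11724 genes, the only 1 of 35 splits to reach it. The highest other, the split by library series, gave 518. A share of 1 of 35 is the smallest that these splits allow. The other splits also leave the tissue difference in the residual spread, which lowers their counts, so the splits alone could not exclude chance. For stage 3 of 35 splits gave as many as the real 313, so this count could not exclude chance. The other 2 were the tissue split (9244, the highest) and the split by library series (1296), and the remaining splits gave 0. The tissue split was fitted without the tissue term of the real stage fit, so 9244 and 313 come from unlike models. The series split kept that term, and its count points to a structure of the samples beyond stage. With the series as a block the stage count was 2632. The other real counts were 0, which every split reaches, so their splits say nothing about chance. For T157 against Richland 35 of 35 splits reached it. The highest other was 15193, from the split into early and late stages, which was fitted without the stage block. W44 against W43 likewise had 0, reached by 100 of 100 splits drawn. The highest other was 15425, for splits that put the 10-50 and 25-50 mg stages on 1 side and divide W44 from W43 only at 50-100 mg. Other drawn splits that divide W44 from W43 only at 50-100 mg gave 0. Those splits moved 300-400 or 400-500 mg to the other side, where the W55 libraries also entered the estimate, so they fit another contrast. The count of 15425 rests on the 50-100 mg pair, which holds the W44 library named above. Whether that library gave the count was not tested. The difference between the T157 and W44 effects had 0, reached by 100 of 100 drawn, with 110 for late against early pairs.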

How the results depend on the processing

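Alternatives that use the model numbered 1, scaling without chromosome 13 models or over described models, the 20% limit without the root pair, and the line-pair sums were chosen after seeing the data. With a pseudocount of 0.1 the counts were 0 for the change of the hilum effect with stage, 619 for stage and 2 for T157 against W44 effects. With no filter they were 21, 0, 5 for W55 and 37250 for W55 coat against whole seed. Rescaling gave 6 for W55 and 11490 for coat against whole seed, and log2 −1.249 for the chalcone synthase sum in the hilum (exact permutation p = 0.0571). Scaling without the chromosome 13 models gave 6 for W55, and scaling over described models 12984 for coat against whole seed. The library series as a block gave 93 for the stage change of the hilum effect and 2632 for stage. The 10-50 and 50-100 mg pairs alone gave 2 for W44, and the 4 late libraries alone 0 for W55. The lost run held 3 genes without the root pair, 16 at 20% without the root pair, and 1 in the remaining settings. For all other counts the cause was not tested.

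Leaving out each library gave 8028 to 11801 for hilum, 0 to 0 for its stage change, 0 to 50 for stage, 0 to 0 for T157, 0 to 1 for W44, 0 to 1.7e+02 for W55 (1.88 times the 88 of all libraries), 0 to 1 for the T157 and W44 difference, 18276 to 25970 for coat against whole seed and −1.62 to −1.069 for the hilum chalcone synthase sum. Leaving out a pair gave 2.297 to 2.703 for the T157 sum and 1.093 to 1.581 for W44, and scaling over described models gave 2.519 and 1.579. Where a group was left with 1 library, that library was assumed to vary like the others.

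Among genes in the W55 coat against whole seed comparison, signs reversed on rescaling for Glyma.15G001700 (0.641), Glyma.13G372000 (0.781), Glyma.17G045800 (0.564), Glyma.14G140400 (0.189) and Glyma.13G161600 (0.221), without the chromosome 13 models for Glyma.15G001700 (0.152) and Glyma.13G372000 (0.297), and over described models for Glyma.15G001700 (0.469), Glyma.13G372000 (0.620) and Glyma.17G045800 (0.199). These follow from the shift of all genes. For named genes in all comparisons, a pseudocount of 0.1 left 401 on the same side of the threshold, 13 weaker and 5 stronger, no filter 339 and 80 weaker, rescaling 373 and 46 weaker, and leaving out 1 library 3328 and 541 weaker. The block on the numbers in the titles gave 23968 for coat against whole seed, whose same-numbered libraries did not vary together (correlation of −0.08 across genes). The young W55 coats had 13 M and 21 M alignments in described models.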

Other observations

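No tests are reported here, and these libraries had 1 replicate each. UC9, a Clark line labelled with the 138 kb deletion, had a chalcone synthase sum of 558 RPKM in coats of 5-6 mg, 26.3 of it in the chromosome 8 copies and 92.7% in the chromosome 1 and 11 copies. RM38, a Clark line with the i allele, had 28.5 in the chromosome 8 copies and 94.5% in the chromosome 1 and 11 copies. Reads shared by several copies can be counted more than once in these sums and shares. The Harosoy lines UC501 and UC508 had sums of 99.5 and 86.7, and the Williams flower 145.6.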
